A study of Homo sapiens with 4 samples.

How the data were processed

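The series holds 4 RNA-seq libraries of J.gamma1 cells, 2 from cells given 10 µM FB23-2 and 2 from cells given the DMSO vehicle at under 0.1%, both collected after 48 h. Per the labels' protocols, the replicates of a group were independent biological samples, total RNA was extracted with Trizol, and libraries were made from 1 µg with an Illumina TruSeq RNA kit. The values used are the whole-number counts per gene that the authors deposited as 1 table of all libraries, with no normalization. HISAT2 2.2.0, StringTie and the hg38 genome build are named in the submitters' processing notes. The StringTie version, the annotation release, the strand setting and the step that turned alignments into counts are not given in the sources used here. Whether the counts are of reads or were derived from StringTie coverage is therefore open, and 497 IDs have a count of 1 in each library. Without a stated strand setting, reads of genes that overlap on opposite strands cannot be told apart.

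The table lists 64252 Ensembl gene IDs, of which 30274 have a count of 0 in all libraries. Names came from a separate list of gene symbols, or from GENCODE release 29 where that list gave none. Coordinates and gene types came from GENCODE release 29, on the same genome build. In it 56591 IDs were found. The other 7661 IDs, which had no coordinates, stayed in the main test and took 1.83% to 1.92% of the counts of a library. Every value column matched the title of 1 sample. Library totals were 37804516 and 33983246 counts for FB23-2 and 24615359 and 34897961 for control, so that 3 counts correspond to 0.0785 to 0.125 CPM. Intervals and floors from counts cover counting error only.

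Replicates were compared before use. Over genes with at least 20 counts, the chi-square per degree of freedom was 6.69 between the FB23-2 libraries and 7.48 between the control libraries, against 74.6 to 82.3 between libraries of different groups, so that no library was a copy of another.

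Genes were kept by filterByExpr of edgeR 4.0.16 (minimum count 10), which left 18817 genes with at least 99.9% of the counts of each library. Libraries were scaled by TMM, and groups were compared with the quasi-likelihood test (glmQLFit with robust dispersions and the version 4 method, then glmQLFTest) in R 4.3.3. Adjusted p values are Benjamini-Hochberg values over all tested genes, and 0.05 was the threshold. The SE of a log2 fold change was computed as its absolute value over the square root of the F statistic. With the common dispersion, the biological coefficient of variation was 10.5%. CPM values were computed after TMM scaling.

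A set of 40 gene lists was fixed before the data were examined, 38 of which had the 5 tested members needed for a list test. They were tested on log2 CPM (prior count 2) with camera of limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. With 2 libraries per group an estimated correlation is itself imprecise. That form of camera also tests on the few residual degrees of freedom. Heat shock genes had an estimated correlation of -0.0159, below the preset, yet their unadjusted camera p went from 2.6e-05 to 0.0451. A call lost under this form is therefore not, by itself, evidence that correlation between genes made the call. Named genes followed a rule also fixed before the data were examined. It took a set of genes of the m6A, MYC and T-ALL literature. It added the 12 highest and the 12 lowest log2 fold changes among genes past the threshold at a mean of 5 CPM or more, with groups that did not overlap. Names of clones, uncharacterised loci and mitochondrial genes were passed over there, 1 among the highest and 3 among the lowest. From each list that passed, it took up to 4 members in the direction of the list and up to 2 called in the other, and from each other list up to 2. Last, it took the 6 most abundant changed genes. List members named without a value, the natural killer marker and the overlapping genes were outside this rule and were chosen after their values were seen.

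The fit was tested on simulated counts for the 18817 genes, with 50 genes changed at each of 4 fold sizes. It recovered 82% of genes changed 4-fold, 60% at 2-fold, 50% at 1.5-fold and 26% at 1.25-fold. Among unchanged genes, 4.87% had an unadjusted p below 0.05, and 18 were called. These made up 14.2% of calls, above the share that an adjusted p of 0.05 aims for. Few genes were changed in that simulation, and whether this accounts for the excess was not tested. A list shifted by 1.3-fold was called, and 0 of 39 random lists were. Genes were drawn independently there, and no gene outside the shifted list was changed. The simulation therefore cannot tell how often camera calls a list falsely where members are correlated or many other genes change. In the data, cytosolic ribosomal protein genes had an estimated correlation of 0.56.

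Alternatives fixed before the data were examined covered scaling (size factors of DESeq2, upper quartile, library size only), DESeq2 1.42.0 in 2 forms, limma-voom, the legacy and the non-robust forms of the quasi-likelihood test, no filter, a mean of at least 1 CPM, a test against a fold of 1.5, the replicate number as a block and each library left out. Chosen after seeing the data were a fit on IDs in GENCODE 29 only, a fit without mitochondrial genes, and offsets that removed each library's loess trend (span 0.5) with GC content and transcript length. A few genes named by the rule are not reported here. Exon overlap of named genes was computed from GENCODE 29: of 168 tested named genes, 84 shared exon bases with another annotated gene, 27 on the same strand and 63 on the opposite strand.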

Results

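RNA was sequenced from J.gamma1 cells, a derivative of the Jurkat human T-cell acute lymphoblastic leukaemia (T-ALL) line that is known to lack the signalling enzyme PLCG1. The cells were cultured for 48 h with 10 µM FB23-2 or with the DMSO vehicle alone at under 0.1%. FB23-2 is a small-molecule inhibitor of FTO, an enzyme that removes N6-methyladenosine (m6A) marks from RNA. Each group held 2 biological replicates, and the deposited table gave 37804516 and 33983246 counts in the FB23-2 libraries and 24615359 and 34897961 in the control libraries. The mitochondrial genome took 6.38% ± 0.017 (SD, n = 2) of counts with FB23-2 and 6.10% ± 0.203 (SD, n = 2) in control. The comparison asked which transcripts change when T-ALL cells are exposed to the FTO inhibitor, with MYC as a gene of interest. Levels below are CPM, counts scaled to library size after TMM normalization, as mean ± SD of 2 libraries per group, and log2 fold changes are FB23-2 over control with their standard error (SE).

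MYC RNA, which encodes a transcription factor that drives growth and ribosome production, fell from 367 ± 1.08 CPM in control to 62.5 ± 5.64 CPM with FB23-2. The log2 fold change was -2.55 ± 0.06 (edgeR adjusted p = 3.77e-08), and MYC lies at chromosome 8, 127735434 to 127741434 of hg38 (ENSG00000136997). FTO itself, at chromosome 16, 53701692 to 54158512, stood at 61.8 ± 1.44 CPM with FB23-2 and 55.9 ± 0.0214 CPM in control. Its log2 fold change of 0.14 ± 0.06 did not pass (edgeR adjusted p = 0.0738), except with scaling by library size alone, where the adjusted p was 0.0238 in a range of 0.0238 to 1 over the alternatives. Across the transcriptome, 7917 of 18817 tested genes changed, 4097 higher and 3820 lower. Of these, 571 were at least 2-fold higher and 840 at least 2-fold lower, and the median absolute log2 fold change of changed genes was 0.50.

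Among transcripts named as FTO targets in leukaemia work, 3 of 5 tested fell and 0 rose, with the same counts adjusted over the list alone. Besides MYC, these were LDHB, a lactate dehydrogenase subunit (-1.01 ± 0.04), and PFKP, a phosphofructokinase (-0.51 ± 0.04). CEBPA (-0.15 ± 0.14) and RARA (0.06 ± 0.13) did not pass. ASB2 had 2 counts in 1 FB23-2 library and 0 in the other libraries, LILRB4 had 0 counts in all 4, and neither was tested. Neither these counts nor the list test take account of whether FTO is thought to raise or lower each member. The list was lower than other genes (camera adjusted p = 0.0294, or adjusted p = 0.548 with an estimated correlation). Its camera adjusted p was 0.119 without FB23-2 replicate 2 and 0.0551 without control replicate 2, in a range of 0.00966 to 0.548 over the alternatives.

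Writers, erasers and readers of m6A moved in both directions: of 21 tested genes, 4 were higher and 6 lower, the same counts as adjusted over the list alone. The methyltransferases METTL3 (-0.51 ± 0.06) and METTL16 (-0.53 ± 0.06) and the reader HNRNPA2B1 (-0.53 ± 0.04) fell. The METTL3 partner METTL14 (0.23 ± 0.06) and the demethylase ALKBH5 (0.25 ± 0.05) rose. WTAP and ZC3H13 were also higher. The METTL14 call was lost without FB23-2 replicate 1 (edgeR adjusted p = 0.0613), without control replicate 1 (0.0747) and after removal of trends with GC content and length (0.156), in a range of 0.00319 to 1 over the alternatives. Of the readers, IGF2BP1 fell (-0.24 ± 0.05), with an edgeR adjusted p of 0.0689 without control replicate 2 and a range of 0.000905 to 1 over the alternatives. YTHDF2 passed narrowly (-0.14 ± 0.05, edgeR adjusted p = 0.0448). It lost its call under 8 alternatives besides the test against 1.5-fold, among them those without FB23-2 replicate 2 (adjusted p = 0.226), control replicate 1 (0.101) and control replicate 2 (0.215), in a range of 0.0149 to 1. YTHDF1 (0.00 ± 0.06), IGF2BP2 (0.20 ± 0.29) and IGF2BP3 (0.06 ± 0.07) did not pass. YTHDF3 (-0.11 ± 0.05) passed only with upper quartile scaling (adjusted p = 0.0387) and after removal of trends with GC content and length (0.0024), in a range of 0.0024 to 1. The list as a whole did not pass camera (adjusted p = 0.745), and its median (0.00) lay on the other side of 0 from its mean (-0.04).

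**Figure D1:**
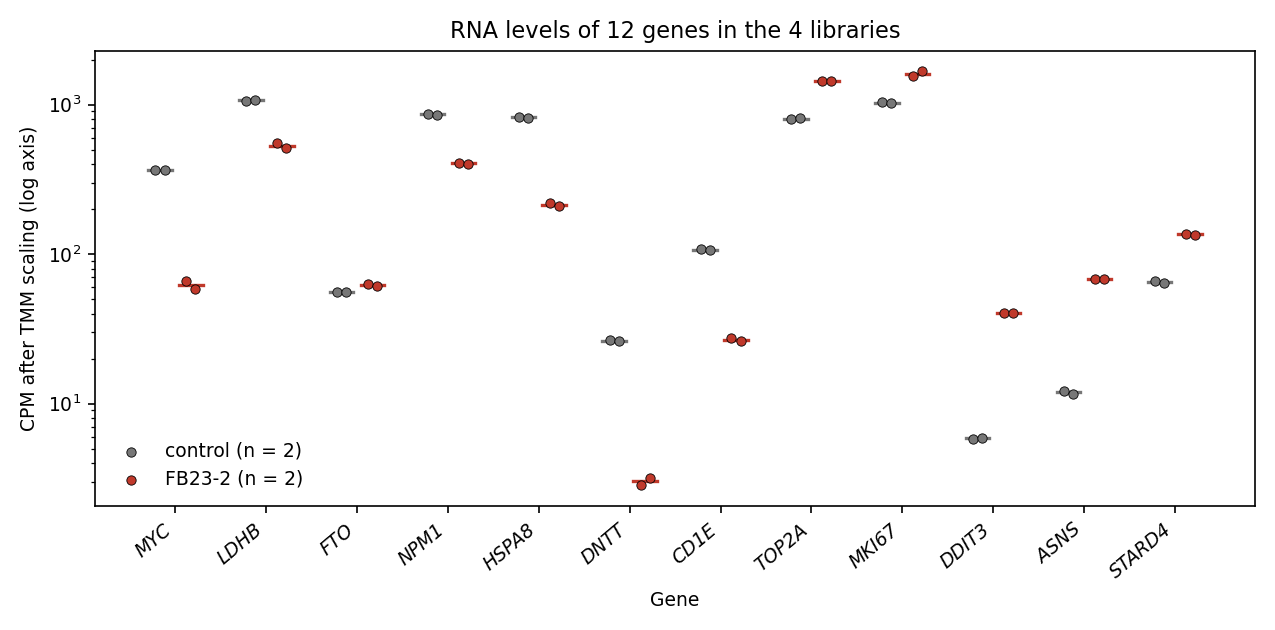
RNA levels in CPM (log axis) of 12 genes, with a point for each library and a bar at the mean of the 2 libraries per group, control in grey and FB23-2 in red. MYC stood at 367 CPM in control and 62.5 CPM with FB23-2, whereas FTO stood at 55.9 and 61.8 CPM.

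The nucleolar and growth genes that MYC is known to induce fell together, with 53 of 57 tested members lower and 2 higher. They included NPM1, a nucleolar chaperone, which went from 860 ± 8.35 to 404 ± 4.65 CPM (-1.09 ± 0.04). NOP56, a core protein of nucleolar ribonucleoprotein particles (-1.32 ± 0.05), the nucleolar protein MYBBP1A (-1.74 ± 0.06) and the mitochondrial chaperone HSPD1 (-1.15 ± 0.04) also fell. HK2, a hexokinase (0.55 ± 0.05), and PLK4, a centriole kinase (0.19 ± 0.05), were the members that rose. PLK4 did not pass without FB23-2 replicate 2 (edgeR adjusted p = 0.0502), control replicate 1 (0.0589) or control replicate 2 (0.0902), nor after removal of trends with GC content and length (0.141), in a range of 0.0031 to 1. The list median was -0.93 (camera adjusted p = 5.44e-18, or adjusted p = 0.462 with an estimated correlation), and 24 members were at least 2-fold lower.

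Other parts of the protein synthesis machinery fell as well. Of 79 cytosolic ribosomal protein genes, 56 were lower and 1, RPS4X (0.18 ± 0.03), was higher, against 60 and 2 adjusted over the list alone. RPS4X did not pass without control replicate 2 (edgeR adjusted p = 0.0603, range over the alternatives 1.48e-05 to 1). RPL6 went from 1493 ± 33.8 to 882 ± 16.8 CPM, and RPL41 (-0.89 ± 0.04), RPL23 (-0.75 ± 0.04) and RPS6 (-0.66 ± 0.04) moved by like amounts. The list median was -0.48 (camera adjusted p = 8.07e-13, or adjusted p = 0.548 with an estimated correlation). Of 72 mitochondrial ribosomal protein genes, 49 were lower and 2 higher, against 51 and 4 adjusted over the list alone, for a median of -0.34 (camera adjusted p = 3.85e-08, or adjusted p = 0.503 with an estimated correlation). MRPL24 (-0.94 ± 0.07), MRPL3 (-0.87 ± 0.06), MRPS25 (-0.76 ± 0.06) and MRPS27 (-0.70 ± 0.06) were among them. MRPL53 (0.28 ± 0.08) and MRPS6 (0.25 ± 0.06) were higher. With any 1 library left out, the edgeR adjusted p of MRPL53 was 0.0752 to 0.111, and DESeq2 did not call it (0.0814 and 0.0856), in a range of 0.000985 to 1 over the alternatives. MRPS6 did not pass without FB23-2 replicate 1 (0.0773), control replicate 1 (0.0524) or control replicate 2 (0.0951), in a range of 0.00484 to 1. MRPL53 shares 45.2% of its exon bases with CCDC142 on the same strand, which fell from 12.6 to 6.49 CPM (-0.94), so its rise is uncertain. MRPS6 shares 6.4% with SLC5A3 on the same strand, which rose from 205 to 317 CPM (0.63), so its rise is uncertain as well. MRPS25 shares 22.2% with NR2C2 on the opposite strand.

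Host genes of small nuclear and nucleolar RNAs, whose introns carry guide RNAs for ribosomal RNA, fell in 13 of 16 cases and rose in 0. SNHG3 went from 65.7 ± 2.15 to 12.7 ± 1.02 CPM (-2.37 ± 0.08), and DANCR (-1.78 ± 0.06), SNHG15 (-1.66 ± 0.07) and GAS5 (-1.39 ± 0.05) followed. For these host genes the median was -1.01 (camera adjusted p = 1.19e-06, or adjusted p = 0.462 with an estimated correlation). Genes of purine synthesis fell in 16 of 18 cases and rose in 0, among them PFAS (-1.38 ± 0.07), ATIC (-1.01 ± 0.05), PAICS (-0.96 ± 0.04) and MTHFD1 (-0.65 ± 0.04). Their median was -0.53 (camera adjusted p = 3.55e-06, or adjusted p = 0.462 with an estimated correlation). Pyrimidine synthesis did not pass camera as a list (adjusted p = 0.0669), except with no filter (0.0311, in a camera range of 0.0311 to 0.548 over the alternatives). Fry called it (adjusted p = 0.0101). It had 9 genes lower and 5 higher (TK1, CMPK1, DCK, TYMS and UCK1) of 17. DHODH, which catalyses the mitochondrial step of that pathway, fell from 24.1 ± 1.28 to 12 ± 0.846 CPM (-1.0 ± 0.10). The nucleoside diphosphate kinases NME1 (-1.47 ± 0.06) and NME2 (-0.93 ± 0.04) fell too, although both share exons with an annotated read-through gene.

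Heat shock genes fell in 14 of 18 cases, and 1, the co-chaperone BAG3 (0.57 ± 0.07), rose. HSPA8, the constitutive HSP70 chaperone, went from 823 ± 11.6 to 214 ± 5.94 CPM (-1.94 ± 0.04). The HSP90 genes HSP90AB1 (-1.59 ± 0.03) and HSP90AA1 (-1.07 ± 0.03) also fell. The heat shock median was -0.61 (camera adjusted p = 1.14e-04, or adjusted p = 0.462 with an estimated correlation). Chaperones of the endoplasmic reticulum and its degradation pathway did not pass as a list (camera adjusted p = 0.327), with 10 genes higher and 8 lower of 24, and EDEM1 (0.50 ± 0.04) and SEL1L (0.51 ± 0.04) rose.

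In glycolysis, 16 of 23 genes were lower and 4 higher. ENO1 (-0.92 ± 0.03), PGK1 (-1.13 ± 0.04), LDHA (-0.59 ± 0.03) and LDHB fell, while the glucose transporter gene SLC2A3 (1.55 ± 0.10), HK2, SLC16A3 and ENO2 rose. The list median was -0.45 (camera adjusted p = 0.00112, or adjusted p = 0.548 with an estimated correlation). Nuclear genes of the respiratory chain had a smaller median of -0.15, with 27 lower and 3 higher of 59 (camera adjusted p = 0.00729, or adjusted p = 0.768 with an estimated correlation). ATP5MC1 (-0.97 ± 0.06), UQCRFS1 (-0.58 ± 0.06), NDUFV2 (-0.45 ± 0.05) and ATP5F1B (-0.30 ± 0.04) fell, and COX8A (0.54 ± 0.05), NDUFC2 (0.27 ± 0.05) and SDHD rose. That list lost its call without FB23-2 replicate 2 (camera adjusted p = 0.119) and after removal of trends with GC content and transcript length (0.331), in a range of 0.00153 to 0.768. Transcripts of the mitochondrial genome did not pass (camera adjusted p = 0.354): 6 were lower and 4 higher of 13. MT-CYB (-0.74 ± 0.04), MT-CO3 (-0.64 ± 0.05) and MT-ND2 (-0.55 ± 0.04) fell, while MT-CO1 (0.35 ± 0.03) and MT-ND4 (0.30 ± 0.04) rose. MT-ND6 was also higher. MT-ND5 (0.15 ± 0.04) passed, but not without FB23-2 replicate 1 (edgeR adjusted p = 0.0739) or control replicate 2 (0.145), in a range of 3.49e-05 to 1. MT-CO1 was the most abundant changed gene, at 16833 ± 212 CPM with FB23-2 and 13164 ± 132 CPM in control. EEF1A1 (-0.26 ± 0.03) and ACTB (-0.15 ± 0.03) were also among the 6 most abundant changed genes, and the ACTB call was lost without control replicate 2 (edgeR adjusted p = 0.112, range over the alternatives 1.59e-04 to 1).

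Genes of the ATF4 and amino acid response, which cells switch on when amino acids run short or translation initiation is inhibited, rose in 26 of 41 cases and fell in 6, against 27 and 6 adjusted over the list alone. DDIT3, which encodes the stress transcription factor CHOP, went from 5.85 ± 0.111 to 40.4 ± 0.119 CPM (2.78 ± 0.10). ASNS, asparagine synthetase, went from 11.9 ± 0.312 to 68.1 ± 0.210 CPM (2.52 ± 0.08), and TRIB3 (1.94 ± 0.07) and the alanyl-tRNA synthetase gene AARS1 (1.26 ± 0.04) rose. The proline synthesis genes PYCR1 (-0.79 ± 0.07) and ALDH18A1 (-0.71 ± 0.05) fell. Across the list the median was 0.49 (camera adjusted p = 1.14e-04, or adjusted p = 0.462 with an estimated correlation). DDIT3 shares 27.2% of its exon bases with a gene on the opposite strand, MARS1, which stood at 198 CPM with FB23-2 and 199 CPM in control.

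Cholesterol synthesis and uptake genes rose in 16 of 24 cases and fell in 4, or 5 adjusted over the list alone. STARD4, a sterol transfer protein, went from 65.0 ± 1.82 to 135 ± 2.33 CPM, and IDI1 (0.60 ± 0.06), FDFT1 (0.46 ± 0.04) and INSIG1 (0.36 ± 0.03) also rose. FDPS (-0.25 ± 0.04), LSS (-0.43 ± 0.05) and NSDHL were among those that fell. The median was 0.33 (camera adjusted p = 0.00893, or adjusted p = 0.462 with an estimated correlation). Fatty acid synthesis (5 higher and 3 lower of 11, camera adjusted p = 0.663) and fatty acid oxidation (6 higher and 0 lower of 12, camera adjusted p = 0.0873) did not pass. FASN (-0.90 ± 0.06), SREBF1 and ACACA fell, ACSS2 (0.64 ± 0.08), FADS1, FADS2, ELOVL5 and ACSL3 rose, and of the oxidation genes ACADVL (0.33 ± 0.04) and CREB3L3 (1.31 ± 0.18) were among those that rose. Autophagy and lysosome genes rose in 20 of 35 cases and fell in 0. They included MAP1LC3B (0.71 ± 0.05) and GABARAPL1 (0.83 ± 0.06) of the autophagosome membrane, the lysosomal membrane protein LAMP2 (0.55 ± 0.04) and WIPI1 (1.87 ± 0.14). The median was 0.26 (camera adjusted p = 4.67e-05, or adjusted p = 0.466 with an estimated correlation). WIPI1 shares 24.3% of its exon bases with ARSG on the opposite strand, which rose as well (0.63).

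**Figure D2:**
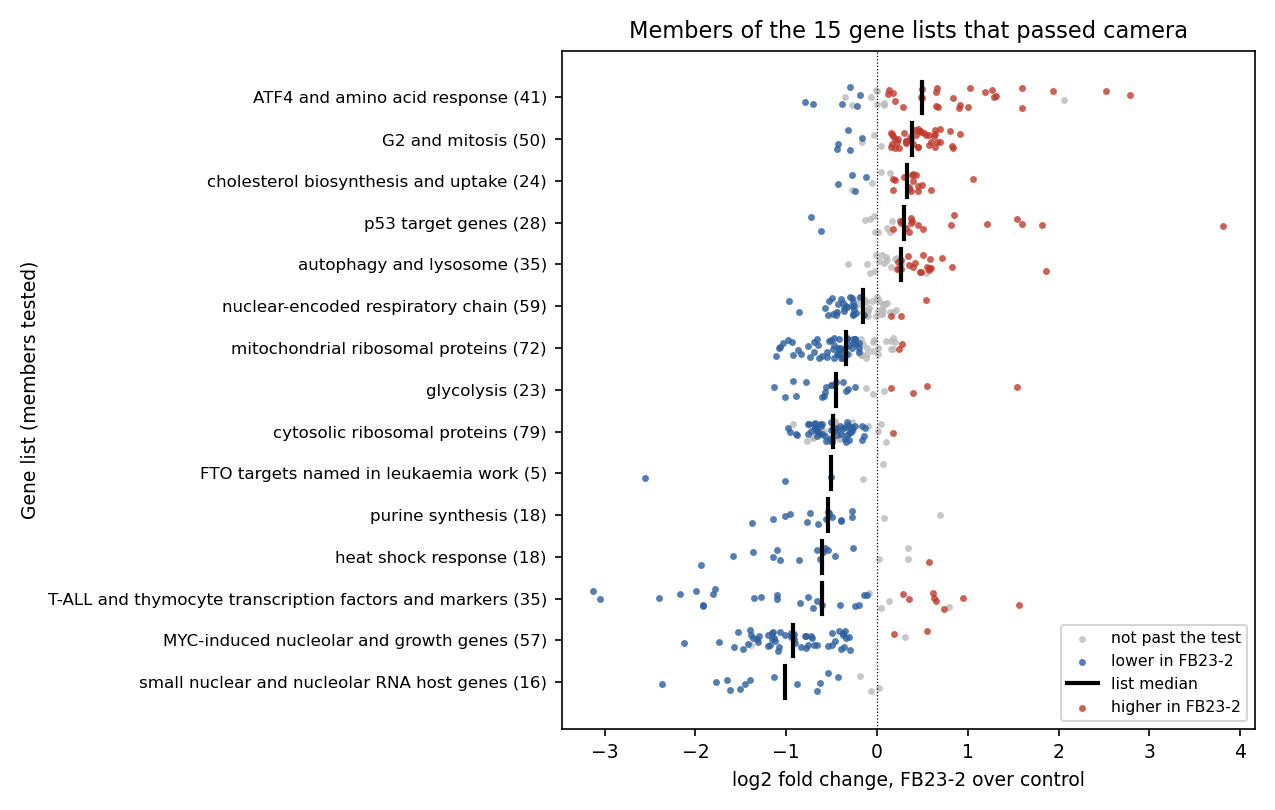
Log2 fold change (FB23-2 over control) of each tested member of the 15 gene lists that passed camera, a point per gene, red where higher, blue where lower and grey where not past the test, with a black bar at the list median. Medians run from -1.01 for host genes of small nuclear and nucleolar RNAs to 0.49 for the ATF4 and amino acid response.

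G2 and mitosis genes rose in 42 of 50 cases and fell in 5. TOP2A, the topoisomerase that resolves chromosomes, went from 807 ± 17 to 1436 ± 8.62 CPM (0.83 ± 0.03). The proliferation marker MKI67 (0.64 ± 0.04), NUSAP1 (0.83 ± 0.04), KIF11 (0.64 ± 0.04) and NCAPG (0.64 ± 0.04) rose, while CCNB1, cyclin B1 (-0.42 ± 0.05), KIF20A (-0.44 ± 0.07), PLK1, CDC20 and MAD2L1 fell. NCAPG shares 33.1% of its exon bases with LCORL on the opposite strand. The list median was 0.39 (camera adjusted p = 6.48e-08, or adjusted p = 0.462 with an estimated correlation). DNA replication genes split, with 17 higher and 14 lower of 50, or 19 and 18 adjusted over the list alone (camera adjusted p = 0.909), and the helicase subunits MCM6 (-0.94 ± 0.04) and MCM7 (-0.83 ± 0.04) fell. G1 cyclins, kinases and their inhibitors did not pass as a list (7 higher and 4 lower of 14, camera adjusted p = 0.309). In it the inhibitors CDKN1A (1.21 ± 0.23), CDKN1B (0.61 ± 0.04) and CDKN2D (1.3 ± 0.07) rose, as did RB1 (0.56 ± 0.04), while CDK4, CDK6, CCND1 and CCND3 fell. CDKN1A was low, at 1.97 ± 0.208 CPM in control and 4.65 ± 0.512 CPM with FB23-2.

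Genes known as p53 targets rose in 18 of 28 cases and fell in 2, for a median of 0.30 (camera adjusted p = 4.01e-04, or adjusted p = 0.462 with an estimated correlation). SESN2 (1.6 ± 0.09), TP53INP1 (1.54 ± 0.08), the death receptor gene TNFRSF10B (0.85 ± 0.06) and PMAIP1, a BH3-only death gene (0.81 ± 0.07), rose. AEN (-0.62 ± 0.08) and TRIAP1 (-0.72 ± 0.11) fell. The BCL2 family, which sets the threshold of cell death, did not pass as a list (4 higher and 4 lower of 15, or 6 and 5 adjusted over the list alone, camera adjusted p = 0.803). Its BH3-only members split: BMF (1.41 ± 0.09), PMAIP1 and BBC3 rose, while BAD and BID fell. BCL2L1 and BCL2L2 fell as well. BCL2 (0.26 ± 0.08) rose, but did not pass without FB23-2 replicate 2 (edgeR adjusted p = 0.118), without control replicate 2 (0.19) or with no filter (0.051), in a range of 0.00917 to 1. MCL1 (0.11 ± 0.04) did not pass, except with library size scaling (0.0179) and with a replicate block (0.0442), in a range of 0.0179 to 1. BCL2L11 (0.20 ± 0.07) did not pass either, except under 5 alternatives with adjusted p values of 0.0262 to 0.046, among them that without FB23-2 replicate 1 (0.0278), in a range that reached 1.

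Transcription factors and markers of T-ALL and thymocytes fell in 23 of 35 cases and rose in 8, or 24 and 10 adjusted over the list alone. DNTT, the terminal transferase of immature lymphocytes, went from 26.4 ± 0.115 to 3.03 ± 0.245 CPM (-3.13 ± 0.13). The CD1 family genes of cortical thymocytes CD1E (-2.00 ± 0.06) and CD1B (-1.92 ± 0.08) and the transcription factor gene TCF7 (-0.75 ± 0.04) also fell. TAL1, the oncogenic transcription factor of this leukaemia subtype, fell slightly (-0.25 ± 0.05), while GATA3 (0.62 ± 0.05), LEF1 (0.63 ± 0.03) and STIL (0.95 ± 0.05) rose. The median was -0.61 (camera adjusted p = 0.00289, or adjusted p = 0.466 with an estimated correlation). T cell receptor components and proximal signalling genes did not pass as a list (19 lower and 10 higher of 35, camera adjusted p = 0.0873), although CD3D (-0.76 ± 0.04) and CD6 (-1.21 ± 0.07) fell. PLCG1 RNA was present at 265 ± 0.276 CPM in control and 293 ± 2.49 CPM with FB23-2 (0.14 ± 0.04), which passed. That call was lost without FB23-2 replicate 1 (edgeR adjusted p = 0.0873), control replicate 1 (0.13) or control replicate 2 (0.0932) and with upper quartile scaling (0.0516), in a range of 0.00158 to 1. Notch pathway genes did not pass (8 lower and 4 higher of 20, camera adjusted p = 0.637), NOTCH1 (-0.47 ± 0.06) and PTCRA (-1.92 ± 0.25) were among the lower, and HEY1, HEY2, RBPJ and MAML1 were the higher.

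By size of change among genes at 5 CPM or more, the 12 highest were CD68, SYT11, ZNF467, DDIT3, ASNS, SYNM, GBP5, NBPF3, DACT3, ARRDC3, TREML2 and JDP2, from 3.71 down to 1.94 on the log2 scale. ARRDC3, an arrestin-domain gene, went from 9.36 ± 1.03 to 40.1 ± 0.00414 CPM. The guanylate-binding protein gene GBP5, known as interferon-inducible, went from 4.57 ± 0.344 to 21.1 ± 1.18 CPM. CD68 shares 81.7% of its exon bases with an overlapping transcript on the same strand and is therefore uncertain. The 12 lowest were DNTT, FN1, CAMKV, PVRIG, CCR8, HNRNPA1P21, IGLL1, MYC, APLN, SNHG3, CPNE7 and RGPD2, from -3.13 to -2.18. FN1, which encodes fibronectin, went from 13.1 ± 1.3 to 1.68 ± 0.309 CPM, and the chemokine receptor gene CCR8 from 13.7 ± 1.26 to 1.97 ± 0.176 CPM. IGLL1, a surrogate light chain gene of precursor lymphocytes, went from 90.0 ± 4.80 to 14.8 ± 0.990 CPM. PVRIG shares 80.9% of its exon bases with STAG3, and NBPF3, HNRNPA1P21, IGLL1 and RGPD2 have near-identical relatives, so their reads could be split between copies.

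The other lists did not pass camera, some of them except under named alternatives. Interferon-stimulated genes had 16 higher and 6 lower of 37 (17 and 9 adjusted over the list alone, adjusted p = 0.126), with STAT2 (1.04 ± 0.05) and SAMD9 (0.68 ± 0.06) higher. Of 15 NF-kB and cytokine genes 8 were higher and 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.0669), with CD69 (19.8 ± 1.17 against 8.31 ± 0.366 CPM) and TNFAIP3 (0.44 ± 0.06) among the higher and CD83 the lower. That list passed camera without control replicate 1 (adjusted p = 0.0119), without control replicate 2 (0.0194) and with no filter (0.00378), in a range of 0.00378 to 0.466. Of 23 immediate early genes 9 were higher, JUN (1.53 ± 0.12) and IER5 (0.72 ± 0.07) among them, and 1, DUSP2, lower (adjusted p = 0.0669). They passed camera without control replicate 1 (adjusted p = 0.0414) and with no filter (0.0276), in a camera range of 0.0276 to 0.466. Hypoxia genes had 9 higher and 7 lower of 22 (9 and 8 adjusted over the list alone, adjusted p = 0.663), with P4HA1 (0.84 ± 0.04) higher and FAM162A (-0.54 ± 0.05) lower, and their median (0.04) and mean (-0.08) differed in sign. NRF2 and antioxidant genes had 5 higher (GCLC, GSR, SLC7A11, GPX4 and FTH1) and 5 lower of 21 (adjusted p = 0.663), the lower being TXN (-0.46 ± 0.05), TALDO1 (-0.46 ± 0.05), TKT, ABCC1 and ABCC4. Of 6 aryl hydrocarbon receptor targets 1, TIPARP (0.46 ± 0.08), rose and NQO1 (0.28 ± 0.12) did not pass (adjusted p = 0.112). With no filter the receptor targets passed camera (adjusted p = 0.0445, in a camera range of 0.0445 to 0.496). Metallothioneins and zinc transporters had 1 higher and 2 lower of 6 (adjusted p = 0.663), with SLC30A1 higher and SLC39A10 (-0.51 ± 0.07) and MT1X (-0.81 ± 0.17) lower. MT1X did not pass without control replicate 2 (edgeR adjusted p = 0.0712, range over the alternatives 0.00219 to 0.311). Replication-dependent histone genes, whose mRNAs carry no poly(A) tail, had means over the 4 libraries of 1.42 CPM or below, with 2 higher and 1 lower of 15 (1 and 0 adjusted over the list alone, adjusted p = 0.663). H3C8 (2.35 ± 0.59) and H2BC15 (1.62 ± 0.50) were those higher and H2BC12 the lower. H3C8 did not pass without control replicate 1 (edgeR adjusted p = 0.0756, range 0.00672 to 0.0756), and H2BC15 did not pass with any 1 library left out (0.0618 to 0.133) or with DESeq2 on the same genes (0.114), in a range of 0.0235 to 0.205.

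Markers of other cell types gave no list that passed. Myeloid markers had 1 higher, CD68, and 1 lower, CEBPE (-2.00 ± 0.12), of 7 (camera adjusted p = 0.909), with camera placing the list higher and fry lower. B cell markers had CR2 lower (-1.07 ± 0.19) and none higher of 7 (camera adjusted p = 0.708). Epithelial markers had 0 changed of 9 (camera adjusted p = 0.559), with KRT8 (0.54 ± 0.25) and KRT14 (0.38 ± 0.34) at 3.74 CPM or below in both groups. Fibroblast markers had 2 higher and 2 lower of 7 (camera adjusted p = 0.559), with a median (0.30) and mean (-0.60) of opposite sign. FBN1 rose (0.76 ± 0.09), and COL1A2 fell from 2.36 ± 0.300 to 0.0916 ± 0.13 CPM, with 1 of the FB23-2 libraries at 0. PDGFRA was the other higher and POSTN the other lower marker, both under 1 CPM in each group. Too few natural killer (4) and erythroid (1) markers were tested for a list test, and of these 1, the perforin gene PRF1, was higher (11.4 CPM with FB23-2 and 5.43 CPM in control).

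Gene calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and the groups did not overlap in 70.8% of tested genes, against 33.3% by chance for 2 libraries against 2. The list counts not given a separate value were the same when adjusted over the list alone. With an estimated correlation 0 camera list calls held, and 2 lists had an unadjusted p below 0.05, against 28 lists past fry. That form of camera had few residual degrees of freedom, so its losses do not by themselves point to correlation between genes. Against a minimum change of 1.5-fold, 1112 genes passed, 434 higher and 678 lower.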

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

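The offsets for GC content and length, the fit on GENCODE 29 IDs and the fit without mitochondrial genes were chosen after the data were seen. The 7917 changed genes ranged from 6418 to 8268 over the alternatives that kept all libraries and tested against no change, and with 1 library left out they ranged from 5650 to 6596 (2899 to 3439 higher, 2751 to 3316 lower). Against a fold of 1.5 the count was 1112 (434 higher, 678 lower), because that test asks for a larger change. Shared calls kept their sign in all 19 alternatives, which refit the same libraries, so a change of sign was unlikely from the start. Higher genes made up 51.7% of calls, 57.7% with library size only and 46.2% with upper quartile scaling, and no scaling moved the median log2 fold change by more than 0.0466. Of the 170 named genes, none changed sign among called ones, with the same limit. Outside the test against 1.5-fold, at most 12 lost their call under an alternative, those 12 without control replicate 2.

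The lists that passed camera numbered 15, against 0 with an estimated correlation (2 at an unadjusted p below 0.05, 20 with the preset) and 28 with fry, which asks a different question. Fry gained 14 lists and lost 1. Those gained included m6A machinery (fry adjusted p = 0.023), pyrimidine synthesis (0.0101) and interferon-stimulated genes (0.00477). The form with an estimated correlation has few residual degrees of freedom here, so its losses alone do not show that correlation made the calls. With 1 library left out they ranged from 13 to 17. The respiratory chain list also lost its call with fry (adjusted p = 0.108) and with the offsets for GC content and length (0.331), where its median was close to 0.

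The replicate numbers are shared by the groups, but no label ties equal numbers together. With the replicate number as a block, 8268 genes changed (4238 higher, 4030 lower), of which 7809 were among the 7917, and 15 lists passed. The differences between replicates 1 and 2 in the groups correlated at 0.0623 across genes, and 0.211 among genes at 10 CPM or more.

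Depth limits low genes. The shallowest library held 24615359 counts. ASB2 had 2 counts in FB23-2 replicate 1 and none elsewhere, and LILRB4 had 0 in every library, so neither was tested. Both were as good as absent from the deeper libraries too, so the shallowest library is not the reason.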

Other observations

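Apart from main results of the fixed gene lists, which are restated here, all tests in this part were chosen after the data were seen. Of genes related to MYC, the paralogs MYCN (-0.84 ± 0.15, SE) and MYCL (-0.62 ± 0.15) fell, at 7.13 and 5.78 CPM with FB23-2, as did the neighbouring long noncoding RNA PVT1 (-1.48 ± 0.27). MXD1, a MYC antagonist, went from 13.4 ± 0.0808 to 34.1 ± 0.406 CPM (1.35 ± 0.09, SD and SE, n = 2 per group, edgeR adjusted p = 4.48e-06), and MXD4 also rose (0.42 ± 0.07). Of the other MAX-binding repressors, MGA fell (-0.26 ± 0.07), though not without control replicate 2 (edgeR adjusted p = 0.0982, range over the alternatives 0.000219 to 1). MNT (-0.24 ± 0.10) passed only with upper quartile scaling (adjusted p = 0.046, in a range that reached 1), so the antagonists did not move in a single direction. Their common partner MAX (-0.15 ± 0.06) did not pass, except under 5 alternatives with adjusted p values of 0.0153 to 0.0469, among them that without FB23-2 replicate 1 (0.0194), in a range that reached 1. Of other regulators, FOXO1 (0.95 ± 0.11) and TFEB, a driver of lysosomal genes (0.58 ± 0.11), rose, and FOXO3 (0.17 ± 0.06, edgeR adjusted p = 0.0479) passed under 6 of 18 alternatives besides the test against 1.5-fold, with an adjusted p of 0.0705 to 0.304 with any 1 library left out, in a range of 0.0192 to 1. ATF4 RNA itself fell (-0.39 ± 0.04), while 26 of the 41 genes of its list rose. ATF4 is a member of that list and is counted among the 6 that fell. TFEB is likewise counted among the higher genes of the autophagy and lysosome list. HSF1 (-0.05 ± 0.05) did not pass. These genes were picked after their values were seen.

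A scan of 357 families of protein-coding genes that share the stem of their symbol, with at least 6 tested members, found 28 with a camera adjusted p under the threshold, 21 lower and 7 higher. With an estimated correlation camera called 0 families (2 at an unadjusted p below 0.05), with a lowest adjusted p of 0.871. Few residual degrees of freedom made a call over 357 families unlikely from the start in that form. All 7 GIMAP genes, a cluster on chromosome 7 that encodes GTPases of lymphocyte survival, fell (median -0.98, camera adjusted p = 9.90e-04), from GIMAP1 (-0.67) to GIMAP8 (-2.17). Of 8 CCT genes, which encode the chaperonin for actin and tubulin, 7 fell by 0.70 to 1.02, and CCT6B (0.61 ± 0.43), at 1.80 CPM or below, did not pass. Genes with the stem EIF, translation initiation factors among them (34 lower and 6 higher of 54), and splicing factors (SRSF, 9 lower and 1 higher of 11) leaned lower. Zinc finger genes (ZNF, 135 higher and 54 lower of 412, median 0.15) and DOCK genes (7 higher and 0 lower of 10, median 0.44) leaned higher.

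Ribosomal protein and respiratory chain transcripts are short, and log2 fold change correlated with transcript length (Spearman rho = 0.138) and GC content (-0.138) across 11568 genes, which are not independent replicates. After the trend with length and GC content was removed from each library, the median was -0.39 for cytosolic (-0.48 before) and -0.28 for mitochondrial ribosomal proteins (-0.34 before), and both lists passed camera at its preset correlation (adjusted p = 5.63e-11 and 7.55e-07), which argues against the trend as the whole cause of either fall. Before that removal, the calls were lost at adjusted p = 0.548 and 0.503 with an estimated correlation. For the respiratory chain the median went from -0.15 (quartiles -0.35 and 0.02) to -0.0291 (quartiles -0.26 and 0.12) and the call ended because the shift itself was gone, so a length or GC trend may account for it. The trend was fitted with the falling ribosomal protein genes included. Its removal therefore cannot separate a technical trend from a shared fall of short transcripts. Reads moving to processed pseudogenes would have kept the share of counts on genes and pseudogenes together, but that share was lower with FB23-2 by -1.58 percentage points (5.01% ± 0.189 against 6.59% ± 0.287, SD, n = 2), which argues against such a move and leaves an effect of FB23-2 open as a hypothesis.

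The p53 target list was higher with FB23-2 (camera adjusted p = 4.01e-04, or adjusted p = 0.462 with an estimated correlation). A candidate explanation is that members also known as targets of ATF4 or CHOP (SESN2, BBC3, PMAIP1, TNFRSF10B and GADD45A) carried it. Without these 5 members, 13 of 23 were higher and 2 lower, the median was 0.25, and the list still passed (camera adjusted p = 0.0123, or adjusted p = 0.466 with an estimated correlation), which argues against those members as the whole cause. After removal of the length and GC trend the median was 0.27, which argues against that trend. What raised the remaining genes was not tested, and the classical target MDM2 (-0.02) did not pass.

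CD68 had the highest fold change of the named genes, from 0.820 ± 0.279 to 11.3 ± 3.51 CPM (SD, n = 2). Its exons overlap the transcript AC016876.2 on the same strand, which stood at 52.6 ± 6.85 CPM in control and 24.8 ± 9.11 CPM with FB23-2. The sum of both was not higher with FB23-2, at -17.3 CPM relative to control, so the rise may reflect reads assigned differently between overlapping transcripts. Myeloid cells in the FB23-2 cultures would also bring LYZ, which stood at 0.434 ± 0.243 CPM with FB23-2, far below the 10.5 CPM that CD68 gained, and S100A9 stood at 0.334 ± 0.139 CPM, which argues against such cells. A switch in the transcript made at this locus stays open, since gene counts do not separate it from assignment.

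Of 10477 genes at 10 CPM or more, 65 had the 2 libraries of a group at least 2-fold apart, and 1 of these, SKIL, passed the test. They included read-through genes such as BIVM-ERCC5, at 53.3 and 0 CPM in the FB23-2 libraries and 81.6 and 0 CPM in control. XBP1, a regulator of the endoplasmic reticulum stress response, stood at 54.7 and 32.8 CPM with FB23-2 and at 11.5 and 36.7 CPM in control, and its difference (0.79 ± 0.75) did not pass.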
